A study of Zea mays with 4 samples.

How the data were processed

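Root tips were collected from maize inbred B73 seedlings 3 days after germination. The labels describe the tissue as the last 1 mm of both the primary and the seminal roots of seedlings kept at 28 C under continuous dim light of about 500 lux. Total RNA was depleted of ribosomal RNA and made into strand-specific libraries whose adaptors carried unique molecular identifiers, short random tags that mark each original fragment. The labels name 4 biological replicates of this single group and no second condition. Both root types are named for every sample, so primary and seminal roots could not be separated.

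The deposited values of each library are estimated counts per gene, listed by NCBI GeneID with no normalization. Per the submitters' processing notes, Trimmomatic (versions 0.36 and 0.39 are both listed), STAR 2.7.10b, SAMtools, UMI-tools, deepTools and HTSeq were used. Their order and settings, the genome build, the annotation release, the strand setting of the counting, and whether reads sharing a molecular tag were collapsed before counting are not given in the sources used here. If they were not collapsed, several reads can come from 1 molecule, and every interval and detection limit below covers counting error only. Most deposited values were whole, but 3062 of the 48174 genes had a fractional value in at least 1 library (tolerance 1e-06 of a count), and the origin of these fractions is not given in the sources used here. Values were rounded to whole numbers before any test. Genes with near-identical copies, such as histone, tubulin, actin, ribosomal protein and zein genes, are uncertain as single genes, because the sharing of reads between copies is not described and no sequence was used here. Overlapping antisense genes are uncertain in the same way.

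A further table of the series has 5 columns of values whose names match none of the 4 samples. None of its values was used in any step. Gene names and classes came from the NCBI RefSeq table of the maize assembly Zm-B73-REFERENCE-NAM-5.0, used for names only, in which 48127 of the 48174 GeneIDs were found and 47 were not. No coordinates are printed because the build behind the deposited counts is not named. The files held 0 genes of the plastid or mitochondrial genomes.

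Library totals ran from 9168900 to 14728797 counts. At these totals a gene with no count in a library could still have reached 0.204 to 0.327 CPM (counts of a gene scaled to a library total of 1e6), the level of 3 counts, and a gene with no count in any of the 4 libraries could have reached 0.0584 CPM. Genes were called expressed with edgeR's filterByExpr at its defaults (minimum count 10, minimum total count 15). Levels are CPM of the library total, as mean ± SD over 4 libraries.

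With one group, the comparison open to these data was between genes within the libraries, with the 4 replicates supplying the error. An intercept-only quasi-likelihood model was fitted in edgeR 4.0.16 with the median expressed protein-coding gene of each library as the offset, so that the fitted value is the log2 ratio of a gene to the median gene. Each gene was tested against a 2-fold difference in either direction, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The tool's own threshold test refuses a design with a single column, so the same quasi-likelihood F statistic was formed directly, from the deviance at the nearer 2-fold bound minus the deviance of the fit. The reference gave no transcript lengths, so no correction for length was made, and a longer transcript yields more reads at the same number of molecules. The procedure was tested on simulated counts drawn from the real means and totals, with 40 genes at each known fold among 20770 genes fitted. Of those 40 genes, 40 were called at 0.25-fold, 39 at 3-fold, 40 at 4-fold, 0 at 1.5-fold and 0 at 1-fold, and 2 of 8123 genes inside the 2-fold range were called wrongly. A fitted ratio within 2-fold cannot be called by construction, so the 0 calls at 1-fold and 1.5-fold were nearly set in advance. The simulated spread was the one edgeR estimated from these libraries, so counts that depart from its model were not tested.

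The definitions of the gene lists, list pairs, tests, the rule for named genes and most alternatives were fixed before the data were examined. The 23 lists were histones (core and linker), DNA replication, mitosis, cyclin D, ribosomal proteins (cytosolic and organelle), tubulins and actins, root patterning, root cap, auxin, cytokinin, lignin and secondary wall, root hair, Casparian strip, phloem, nutrient and water uptake, benzoxazinoid synthesis, DNA methylation and small RNA, hypoxia and heat response, and photosynthesis, seed storage, and pollen and anther genes as lists of other tissues. They had been defined by gene descriptions, which the reference does not carry, so membership was rebuilt from gene symbols and synonyms before any level was computed. It covers 446 genes and leaves out every gene known only by a locus number. It also took in kinds of genes that the fixed definitions had not named. Among these were wee1 (mitosis), hp2 (cytokinin), the Yucca genes (auxin) and cesa10 (lignin and secondary wall). Both wee1 and hp2 count among the genes above the median gene in their lists. After levels had been seen, 3 genes were taken out on grounds of their names: a ribosomal protein gene with a replication-like synonym, a gene sharing the spelling of pep1, and an ambiguous methyltransferase name. The named genes were the 10 protein-coding genes with the highest mean level, the highest 2 and the lowest expressed member of each list, all members of lists with at most 15 expressed members, genes fixed by symbol, and the 10 genes with the highest biological coefficient of variation among those at 10 CPM or more.

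The position of a list was the median log2 ratio of its expressed members (pseudocount 0.5 count), as mean ± SD over 4 libraries. It was compared with 10000 random lists of equal size in a two-sided permutation test, adjusted over the 17 lists with at least 3 expressed members, where the smallest unadjusted p is 0.0002. The share of members expressed was compared with all protein-coding genes by a two-sided Fisher's exact test, adjusted over 23 lists. List members all carry a symbol or synonym, whereas all protein-coding genes and the random lists include genes known only by a locus number. A difference may thus partly go with having a name, which was not tested. The 12 list pairs were compared by a two-sided exact sign-flip permutation test over the 4 libraries, whose smallest possible p is 0.13, so no pair could pass 0.05. Genes in a list are not independent replicates. Replicates were compared by Pearson correlation across genes, chi-square per degree of freedom, and the edgeR biological coefficient of variation (BCV), and spread beyond counting error was judged against 1000 multinomial draws.

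Alternatives were edgeR's TMM scaling, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma 3.58.1 with its trend option, other expression filters, no 2-fold threshold, list means, a pseudocount of 1 count, and leaving out each replicate in turn. A version restricted to genes with whole values was added after the data had been seen. Scripts ran in R 4.3.3 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.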

Results

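The data describe the steady-state transcriptome of whole cells in maize root tips, the zone that holds the meristem and the root cap. Tips of primary and seminal roots of 3-day-old B73 seedlings formed 1 group of 4 biological replicates, and the stated purpose was to profile this tissue without a contrasting condition. The total count was 14728797 in replicate 1, 9168900 in replicate 2, 13813025 in replicate 3 and 13621306 in replicate 4. A count was found for 27579, 26777, 27872 and 27883 genes in replicates 1 to 4, and for 30723 genes in at least 1 library. All levels are CPM, the counts of a gene scaled to a library total of 1e6, with the SD over 4 libraries.

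The protein-coding gene with the highest level was grp1 (GeneID 542725), which encodes a glycine-rich protein, at 11265 ± 2109 CPM (SD, n = 4). It was followed by the glutathione S-transferase gene gst5 (GeneID 542734) at 5878 ± 313 CPM, RAB15 at 4561 ± 668 CPM and RP-P0, the gene of an acidic protein of the ribosomal stalk, at 3977 ± 266 CPM. LOC100282150, LOC100284808 and LOC100284901 stood at 3976 ± 215, 3044 ± 554 and 2722 ± 423 CPM. The remaining genes among the first 10 protein-coding genes were gpc4, a cytosolic glyceraldehyde-3-phosphate dehydrogenase gene, at 3096 ± 421 CPM, the adenine nucleotide translocator gene ANT-G1 at 2987 ± 121 CPM and the heat shock protein gene hsp70-4 at 2733 ± 404 CPM. Protein-coding genes took 93.3 ± 1.32% of the counts, and 907 of them held 50% of the protein-coding counts.

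Of 34018 protein-coding genes in the files, 19606 (57.6%) passed the expression filter, among 21046 expressed genes of all classes. The median expressed protein-coding gene stood at 14.6 ± 0.678 CPM (n = 4). Tested with edgeR's quasi-likelihood model against a 2-fold difference from this median gene, 5384 genes lay above it, 5675 lay below it and 9987 did neither at an adjusted p of 0.05. Among protein-coding genes the numbers were 5206 above, 4914 below and 9486 neither. Levels were not corrected for transcript length, so a ratio between genes is one of reads and not of molecules. Without the 2-fold threshold 9312 genes lay above and 9917 below, and without the expression filter, which lowers the median gene, 8745 lay above and 12774 below. Of the named genes, 10 then lost a call below and 18 gained a call above.

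**Figure D1:**
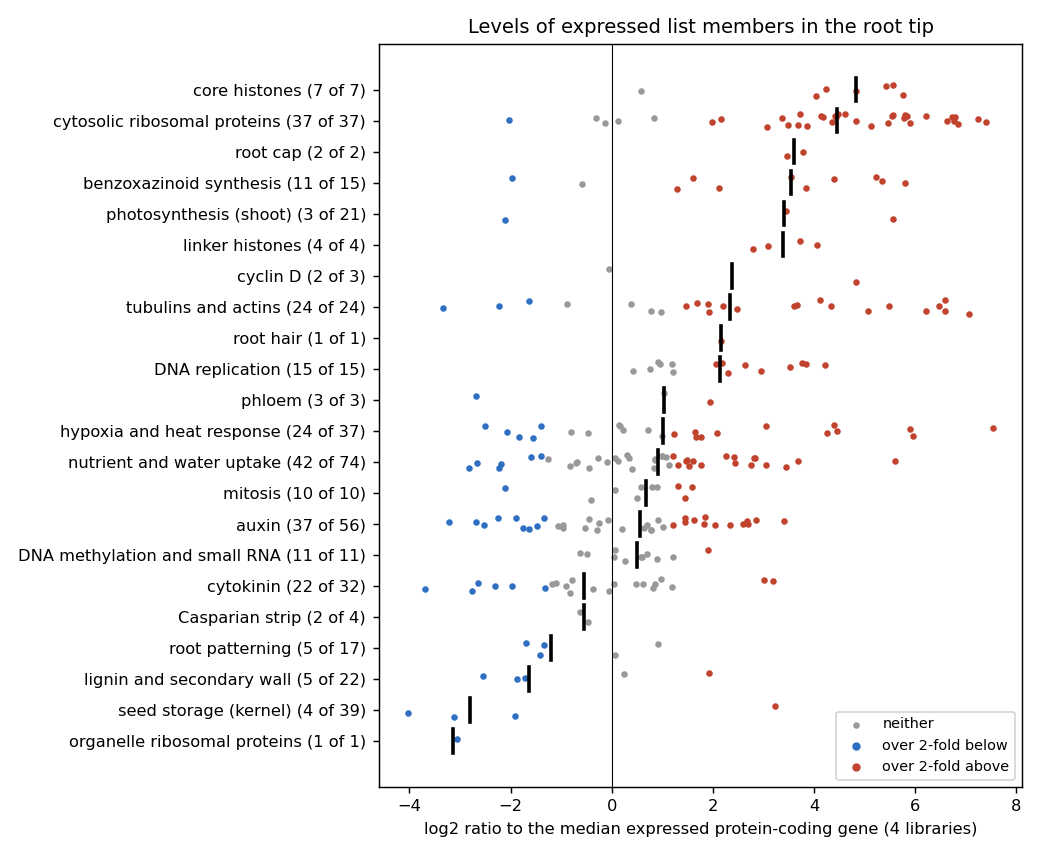
Each point is an expressed member of a gene list, placed by its fitted log2 ratio to the median expressed protein-coding gene over 4 libraries, and coloured by the edgeR test against a 2-fold difference. Vertical bars mark the list medians and brackets give expressed and annotated members; the medians run from 4.82 for core histones to -3.13 for the single organelle ribosomal protein gene.

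Genes of chromatin assembly and DNA synthesis lay far above the median gene. The 7 core histone genes had a median log2 ratio of 4.82 ± 0.17 (SD, n = 4), a 28.3-fold excess, and 6 of 7 passed the test. The histone H4 gene H4C13 stood at 784 ± 179 CPM and the H2B gene his2b5 at 693 ± 70.0 CPM, while cenH3, the centromeric histone H3 variant, reached 21.8 ± 2.31 CPM and did not pass. All 4 linker histone genes lay above, with a median log2 ratio of 3.39 ± 0.13, and hon110 was the highest at 245 ± 43.2 CPM. In the DNA replication list 9 of 15 genes lay above and 0 below, with a median log2 ratio of 2.14 ± 0.09. The sliding clamp genes PCNA (GeneID 542425) and pcna2 stood at 273 ± 16.5 and 199 ± 10.6 CPM, and RNRS1, a small subunit of ribonucleotide reductase, at 209 ± 14.6 CPM. The helicase subunit genes MCM6 and MCM7 reached 66.6 ± 7.30 and 60.9 ± 8.59 CPM. The origin recognition genes orc1, orc2, orc3 and orc4 were lower, between 19.5 ± 3.67 CPM for orc3 and 33.4 ± 4.32 CPM for orc1, and none of the 4 passed over all genes.

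The permutation test against random lists gave adjusted p = 0.00085 for core histones, 0.0112 for linker histones and 0.00612 for DNA replication (n = 4). Adjusted over the list alone, 6 core histone, 4 linker histone and 10 replication genes lay above, the added one being orc1. By edgeR over all genes orc1 had an adjusted p of 0.0522 and SLD5, a gene of the GINS complex of replication forks, one of 0.0911; orc1 passed without replicate 2 (0.00901) but not without replicate 1, 3 or 4 (0.287, 0.0979 and 0.0850), and SLD5 passed without replicate 4 (0.0181) but not without replicate 1, 2 or 3 (0.0614 to 0.397). With a minimum of 1 CPM orc1 (0.0192) and SLD5 (0.0389) both passed, as did SLD5 with whole values only (0.0355) and orc1 with limma (0.0388). Histone genes and the PCNA pair have near-identical copies, so their single levels are uncertain.

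The mitotic genes on the list stood closer to the median gene. Matched by symbol, the list held mainly cyclin, kinetochore and centromere genes and no aurora kinase, kinesin or condensin gene. It thus covers mitosis only in part. In the list of 10, 3 lay above, 1 below and 6 did neither, with the same counts adjusted over the list alone, and the median log2 ratio of 0.68 ± 0.17 did not pass against random lists (permutation test, adjusted p = 0.371, n = 4). The cyclin gene cyc1 stood at 43.8 ± 7.09 CPM, the spindle checkpoint gene mad2 at 39.9 ± 4.86 CPM and wee1, a kinase that restrains entry into mitosis, at 36.1 ± 2.86 CPM. The kinetochore gene MIS12-1 was the lowest at 3.38 ± 0.203 CPM. Of 3 D-type cyclin genes, which act at the start of the cell cycle, cycD2 lay above at 416 ± 32.8 CPM, cycD1 stood at 14.1 ± 2.33 CPM and did not pass, and cycD4 was not expressed, with 10 counts over 4 libraries; adjusted over the list alone, 1 of the 2 expressed members lay above. All 10 mitotic genes and all 15 replication genes were expressed, a larger share than among all protein-coding genes (Fisher's exact test, adjusted p = 0.0173 and 0.00119, or 0.230 and 0.0701 where 1 count sufficed for detection). Both lists hold only genes with a symbol or synonym, which may by itself raise the share and was not tested. The replication list exceeded the mitosis list by 1.46 ± 0.16 log2 units, and core histones exceeded linker histones by 1.43 ± 0.23, both in 4 of 4 libraries. The replication genes above the median gene were those of ribonucleotide reductase, PCNA and MCM subunits. The first difference is thus one between the listed genes and not between replication and mitosis as a whole. For both pairs the exact sign-flip permutation test gave p = 0.13 (adjusted 0.136), the smallest p that 4 libraries allow. With list means the excess of core histones was 0.93.

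**Figure D2:**
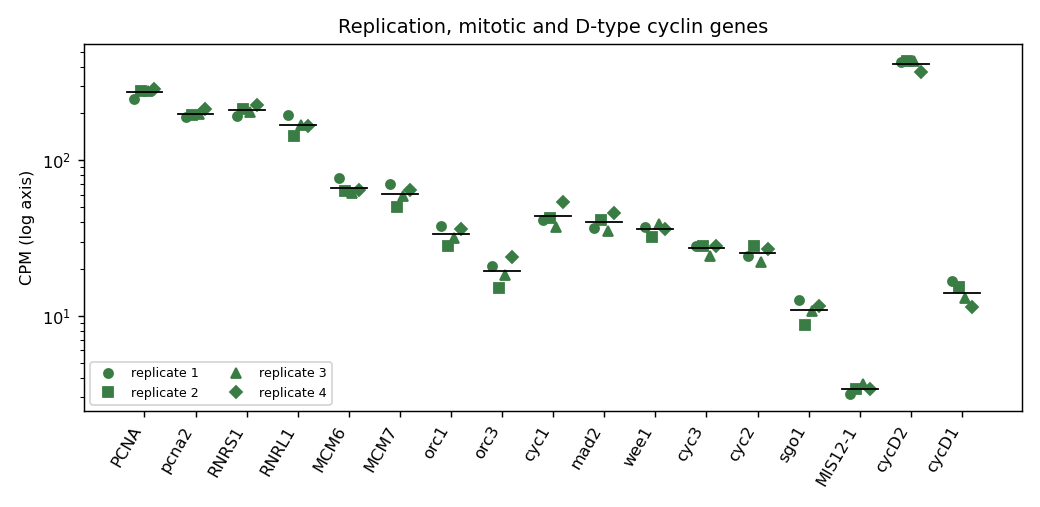
CPM on a log axis for genes of DNA replication, mitosis and cyclin D, 1 symbol per library and a line at the mean of 4. PCNA averages 273 CPM and MCM7 60.9 CPM, the mitotic genes shown reach at most 43.8 CPM (cyc1), and cycD2 at 416 CPM stands apart from cycD1 at 14.1 CPM.

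Genes of the translation machinery and the cytoskeleton were also high. Of 37 genes for cytosolic ribosomal proteins, 32 lay above, 1 below and 4 did neither, and their median log2 ratio was 4.45 ± 0.23, a 21.9-fold excess. RPL10 stood at 2457 ± 164 CPM and rps4 LOC103644306 at 2210 ± 163 CPM, whereas rps10 stood at 3.59 ± 0.209 CPM. The single organelle ribosomal protein gene that could be named, prpl35-1, lay below at 1.72 ± 0.696 CPM, and adjusted over the list alone this 1 gene also lay below. The cytosolic list exceeded it by 7.59 ± 0.43 log2 units in 4 of 4 libraries (exact sign-flip permutation test, p = 0.13, adjusted 0.136). Of 24 tubulin and actin genes 17 lay above, 3 below and 4 did neither, with a median log2 ratio of 2.34 ± 0.25. The alpha-tubulin genes tua4 and tua3 stood at 1951 ± 152 and 1403 ± 86.1 CPM, and the lowest member, actin LOC100273396, at 1.45 ± 0.348 CPM. Adjusted over the list alone, the counts were the same, 32 above and 1 below for cytosolic ribosomal proteins and 17 above and 3 below for tubulins and actins. Both lists lay higher than random lists (permutation test, adjusted p = 0.00085 for each, n = 4), and single members are uncertain because of near-identical copies.

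Markers of the outer tip and of patterning differed widely in level. Both root cap genes lay above, RCP1 (GeneID 541623) at 201 ± 37.2 CPM and RCP2 at 162 ± 17.7 CPM, and so did rth3, a gene of root hair elongation, at 65.6 ± 3.09 CPM. In the root patterning list 5 of 17 genes were expressed and none lay above. Matched by symbol, this list held mostly wox and wus homeobox genes and no PLETHORA or SHORT-ROOT gene. It thus covers root patterning only in part. Its wox and wus genes were taken as a family by name and not for a role in the root. The share expressed and the position of this list therefore do not show that root patterning genes are low in the root tip. Its highest members were rum1-like1, which is also on the auxin list, at 27.6 ± 4.87 CPM and SCR, the maize SCARECROW gene, at 15.3 ± 2.13 CPM. Neither passed the test. The homeobox genes wox13A, wox5B and wox13B lay below at 5.80 ± 1.22, 5.54 ± 1.06 and 4.49 ± 0.536 CPM. No count in any library was found for 9 genes of the root patterning list, rtcs among them, which at this depth allows up to 0.0584 CPM. The Casparian strip and phloem lists were short, and their members differed in level. On the Casparian strip list the CASP-like genes ZmCASPL2D1 and ZmCASPL5A1 stood at 10.6 ± 1.85 and 9.50 ± 0.924 CPM. Neither passed the test, and the other 2 of the 4, ZmCASP1 and ZmCASP2, were not expressed. Among the 3 sucrose transporter genes of the phloem list, sut2 lay above at 55.9 ± 3.07 CPM, sut4 stood at 2.05 times the level of the median gene without passing and sut1 lay below at 2.24 ± 0.844 CPM.

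The median log2 ratio was 3.61 ± 0.14 for root cap, 2.16 ± 0.12 for root hair, 1.03 ± 0.17 for phloem, -0.56 ± 0.20 for the Casparian strip and -1.21 ± 0.25 for root patterning. Adjusted over the list alone, the calls were the same, with 2 above for root cap, 1 above for root hair, 3 below for root patterning, 1 above and 1 below for phloem and 0 for the Casparian strip. Root patterning and phloem did not pass against random lists (permutation test, adjusted p = 0.307 and 0.448, n = 4), and the other 3 lists were too short for that test. With list means phloem stood at 0.01 (adjusted p = 0.972) and root patterning at -0.76 (0.526); with every gene that had a count phloem stood at 1.89 (0.382), root patterning at -0.76 (0.672) and the Casparian strip turned to 0.16. Root cap exceeded root patterning by 4.82 ± 0.18 log2 units in 4 of 4 libraries, and root patterning minus root hair was -3.37 ± 0.21 with all 4 negative (exact sign-flip permutation test, p = 0.13 and adjusted 0.136 for each). DNA replication exceeded the Casparian strip list 6.49-fold, with an SD of 0.21 log2 units, in 4 of 4 libraries (the same exact permutation test, p = 0.13, adjusted 0.136). That contrast rests on the 2 expressed CASP-like genes and not on ZmCASP1 or ZmCASP2. By edgeR, the call of wox13A was lost without replicate 1, 2 or 3 (adjusted p = 0.241, 0.0918 and 0.0951) and that of wox5B without replicate 1, 3 or 4 (0.0758, 0.0954 and 0.0535); wox13A also missed the threshold with DESeq2 (0.0518), a minimum of 1 CPM (0.0573) and whole values only (0.0598).

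Most genes on the lignin and secondary wall list were not expressed. The list held mainly laccase genes, so its share does not describe lignin synthesis as a whole. Of 22 such genes 5 passed the expression filter, 22.7% against 57.6% of all protein-coding genes (Fisher's exact test, adjusted p = 0.00563). ccoaomt1, a caffeoyl-CoA O-methyltransferase gene, lay above at 55.6 ± 16.1 CPM and CCOAOMT2 stood at 17.4 ± 6.04 CPM without passing. The caffeic acid O-methyltransferase gene comt, the laccase gene LAC1 and the cinnamyl alcohol dehydrogenase gene BM1 lay below at 4.41 ± 1.60, 4.01 ± 1.27 and 2.49 ± 0.430 CPM. The counts were 1 above and 3 below adjusted over the list alone as well. The median log2 ratio of the expressed members was -1.63 ± 0.33 and did not pass against random lists (permutation test, adjusted p = 0.185, n = 4). It was -0.90 with the list mean (adjusted p = 0.426), and with every gene that had a count it was -4.70 and passed (adjusted p = 0.00333). The mitosis list exceeded it by 2.31 ± 0.47 in 4 of 4 libraries (exact sign-flip permutation test, p = 0.13, adjusted 0.136), by 1.30 ± 0.37 with list means and by 6.24 ± 0.30 with every gene that had a count. Root patterning exceeded it in 3 of 4 libraries, by 0.42 ± 0.43 (exact permutation p = 0.25, adjusted 0.25). That difference was 0.23 without replicate 2, 0.78 without replicate 3, 0.14 ± 0.33 with list means and 3.94 ± 0.33 with every gene that had a count. When 1 count sufficed for detection, the lignin share was 77.27%, against 77.26% of all protein-coding genes.

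Hormone genes lay on both sides of the median gene. Of 56 auxin genes 37 were expressed, 13 of them above, 9 below and 15 neither, with a median log2 ratio of 0.55 ± 0.12. PIN1a (GeneID 103637824), an auxin efflux carrier gene, led with 155 ± 16.9 CPM, followed by the auxin response factor gene ARF9 at 105 ± 5.42 CPM, and AUX27 was the lowest expressed member at 1.61 ± 0.489 CPM. Of 32 cytokinin genes 22 were expressed, 2 of them above, 6 below and 14 neither, with a median log2 ratio of -0.55 ± 0.20. The phosphotransfer gene hp2 and the response regulator gene RR9 lay above at 134 ± 8.67 and 118 ± 8.70 CPM, and the cytokinin oxidase gene cko lay below at 1.14 ± 0.0592 CPM. With p adjusted over the list alone, 13 auxin genes lay above and 9 below, and 2 cytokinin genes above and 5 below. Neither list passed against random lists (permutation test, adjusted p = 0.185 and 0.307, n = 4). The auxin list exceeded the cytokinin list by 1.10 ± 0.30 in 4 of 4 libraries (exact sign-flip permutation test, p = 0.13, adjusted 0.136), by 0.66 with list means and by 0.73 with every gene that had a count.

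Genes of benzoxazinoid synthesis, the pathway of the main defence compounds of young maize, lay mostly above the median gene. Of 15 genes 11 were expressed, 9 of them above, 1 below and 1 neither, with a median log2 ratio of 3.54 ± 0.17, an 11.6-fold excess. The O-methyltransferase gene Bx7 (GeneID 100147731) stood at 811 ± 75.7 CPM, the beta-glucosidase gene glu1 at 594 ± 137 CPM and the glucosyltransferase genes bx9 and bx8 at 548 ± 9.48 and 306 ± 24.8 CPM. The cytochrome P450 genes BX5, BX4 and BX3 stood at 210 ± 16.7, 171 ± 13.3 and 64.0 ± 6.22 CPM, and the dioxygenase gene bx6 at 44.4 ± 10.8 CPM. The P450 gene bx2, which acts before BX3, lay below at 3.79 ± 1.20 CPM. bx1 (GeneID 542117), the indole-producing lyase that opens the pathway, had 1 count over 4 libraries, where igl1, a paralogous lyase of the same reaction, stood at 35.6 ± 4.08 CPM. BX14 stood at 9.72 ± 2.18 CPM without passing. BX13 and glu2, with 2 and 1 counts, and the gene named Igl (GeneID 100273163) were not expressed. Adjusted over the list alone, 9 lay above and 1 below, and the list lay higher than random lists (permutation test, adjusted p = 0.00085, n = 4).

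**Figure D3:**
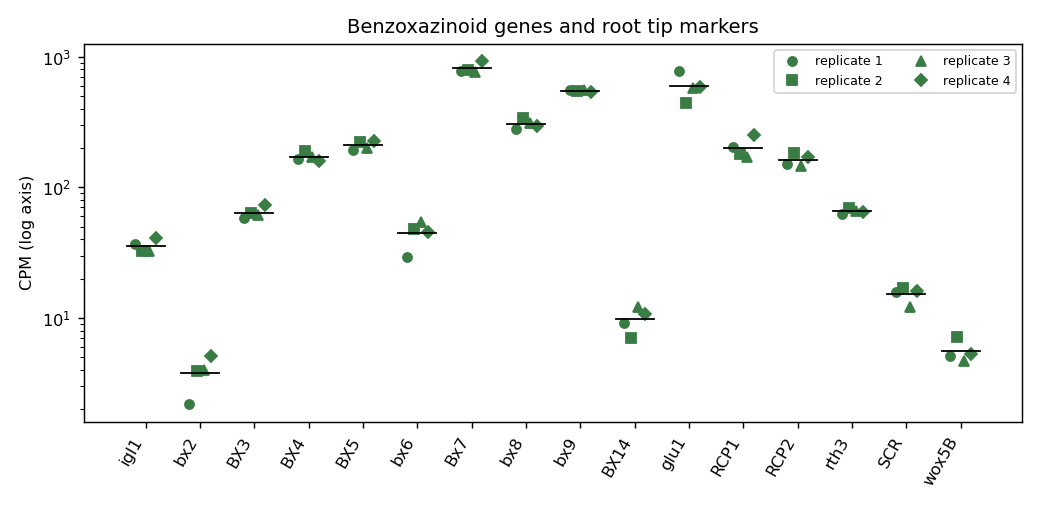
CPM on a log axis for the expressed benzoxazinoid genes and for markers of the root cap (RCP1, RCP2), root hairs (rth3) and patterning (SCR, wox5B), 1 symbol per library and a line at the mean of 4. Bx7 averages 811 CPM and bx2 3.79 CPM; RCP1 at 201 CPM stands above SCR at 15.3 CPM.

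Transporters of water and nutrients had a median log2 ratio of 0.92 ± 0.13, and 42 of 74 genes were expressed, 17 above, 6 below and 19 neither. The plasma membrane aquaporin genes PIP2-6 and PIP2-1 stood at 704 ± 45.3 and 189 ± 31.5 CPM, and the tonoplast aquaporin gene TIP4-2 LOC103635714 was the lowest expressed member at 2.07 ± 0.217 CPM. The numbers were also 17 above and 6 below when adjusted over the list alone. The list lay higher than random lists (permutation test, adjusted p = 0.0225, n = 4), but not when the list mean replaced the median (adjusted p = 0.0591), when every gene with a count was kept (0.582) or when only genes with whole values were used (0.0526). Benzoxazinoid genes exceeded this list by 2.62 ± 0.25 in 4 of 4 libraries (exact sign-flip permutation test, p = 0.13, adjusted 0.136).

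All 11 genes of DNA methylation and small RNA pathways were expressed, a larger share than among all protein-coding genes (Fisher's exact test, adjusted p = 0.0103, or 0.168 where 1 count sufficed), and most stood near the median gene. This list too holds only genes with a symbol or synonym. The DNA methyltransferase gene DMT105 lay above at 55.1 ± 8.23 CPM, and the other 10 did neither. Among these, rmr7 stood at 33.6 ± 7.74 CPM, mop1, an RNA-dependent RNA polymerase gene, at 27.0 ± 2.12 CPM, the Dicer gene dcl1 at 22.2 ± 2.76 CPM and dmt106 at 9.39 ± 1.94 CPM. Adjusted over the list alone, 1 lay above and 0 below, and the median log2 ratio of 0.49 ± 0.24 did not pass against random lists (permutation test, adjusted p = 0.448, n = 4). By edgeR, rmr7 had an adjusted p of 0.106; it was 0.00692 without replicate 2, and 0.952, 0.147 and 0.0957 without replicates 1, 3 and 4. It passed with a minimum of 1 CPM (0.0484) and with whole values only (0.0437).

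Hypoxia and heat response genes included some of the most abundant transcripts. Of 37 genes 24 were expressed, 12 above, 5 below and 7 neither, with a median log2 ratio of 1.00 ± 0.27. Besides hsp70-4, the sucrose synthase gene sus1 stood at 903 ± 258 CPM, ranging from 755 CPM in replicate 2 to 1289 CPM in replicate 1. The alcohol dehydrogenase genes adh1 and adh2 lay above at 121 ± 38.6 and 49.8 ± 6.99 CPM, and the heat stress transcription factor gene Hsf01 lay below at 2.54 ± 0.417 CPM. There were likewise 12 above and 5 below when adjusted over the list alone. The list lay higher than random lists (permutation test, adjusted p = 0.0486, n = 4), but the adjusted p rose to between 0.0578 and 0.0785 when any 1 of the 4 replicates was left out, to 0.0989 with a minimum of 1 CPM, to 0.175 with whole values only and to 0.631 with every gene that had a count.

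Most genes on the lists of other tissues were not expressed. Of 21 photosynthesis genes 3 were expressed (Fisher's exact test, adjusted p = 0.000297), 12 had no count in any library and 6 more fell under the filter. The expressed members were 2 genes of phosphoenolpyruvate carboxylase, an enzyme that also serves tissues without photosynthesis, and 1 chlorophyll-binding protein gene. pep7 and pep4 lay above at 691 ± 164 and 159 ± 37.7 CPM, Cab-m7 lay below at 3.45 ± 1.12 CPM, and pep1, the isoform of leaf photosynthesis, had 1 count over 4 libraries. The list position of 3.41 ± 0.30 (permutation test, adjusted p = 0.0283, n = 4) was the level of pep4, the middle one of the 3 expressed members. It was 2.22 with the list mean (adjusted p = 0.111) and -5.06 when every gene with a count was kept. Of 39 seed storage genes 4 were expressed (Fisher's exact test, adjusted p = 1.96e-08) and 27 had no count. The dehydrin gene dhn2 lay above at 137 ± 21.2 CPM, while the globulin gene GLB1, the oleosin gene ole1 and Lea14A lay below at 3.73 ± 3.73, 1.66 ± 0.609 and 0.913 ± 0.167 CPM. Of 13 pollen and anther genes 0 were expressed (Fisher's exact test, adjusted p = 8.12e-05), 7 had no count and the highest reached 0.956 CPM.

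Adjusted over the list alone, 2 photosynthesis genes lay above and 1 below, and 1 seed storage gene above and 3 below. The seed storage list lay lower than random lists at -2.80 ± 0.74 (permutation test, adjusted p = 0.0112, n = 4), with an adjusted p of 0.0884 and a position of -2.46 without replicate 3. The list mean of -1.66 and the whole-valued genes at -2.31 did not pass either (adjusted p = 0.144 and 0.156, permutation test). By edgeR the call of GLB1 was lost without replicate 2, 3 or 4 (adjusted p = 0.129, 0.0807 and 0.140) and with DESeq2 (0.274), and its log2 ratio moved from -1.90 to -2.83 without replicate 1, where its level was 9.03 CPM. DNA replication minus photosynthesis was -1.27 ± 0.23 with all 4 libraries negative, and photosynthesis exceeded seed storage by 6.22 ± 0.59 in 4 of 4 libraries (exact sign-flip permutation test, p = 0.13 and adjusted 0.136 for each). Both differences turned over when every gene with a count was kept, to 8.07 and -0.88, and with list means they were -0.09 ± 0.20, within its SD, and 3.88.

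The 4 libraries resembled each other across genes, with pairwise Pearson correlations of log2 CPM between 0.979 and 0.990 over 21046 genes, which are not independent replicates. The common BCV from edgeR was 0.129. Each pair of libraries differed by more than counting error, with chi-square per degree of freedom from 6.99 to 19.7. The spread between libraries exceeded counting error for 52.3% of expressed genes, where chance gives 5%, and for 69.3% of those at 10 CPM or more. Of the 10 genes with the highest BCV among those at 10 CPM or more, 5 were genes of small nuclear RNA (snRNA), and these were lowest in replicate 4. LOC111590671 averaged 1444 ± 657 CPM, LOC111591483 1017 ± 451 CPM, LOC111590661 788 ± 372 CPM, LOC111590249 214 ± 103 CPM and LOC111590670 11.4 ± 5.75 CPM. Of the other 5, LOC100281806, LOC103638099, LOC100277944 and LOC103640631 were lowest in replicate 2, at 2.07, 3.60, 7.42 and 3.16 CPM against means of 14.5, 13.2, 30.2 and 10.7 CPM, and LOC100277838 was highest there at 284 CPM against a mean of 151 CPM. By edgeR, LOC100277944 did not pass with all 4 libraries and lay above the median gene without replicate 2 (adjusted p = 0.00328), but not without any other replicate.

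Noncoding classes took a small share of the counts. The snRNA share was 2.25 ± 0.810% (SD, n = 4), the small nucleolar RNA (snoRNA) share 2.37 ± 0.499% and the long noncoding RNA (lncRNA) share 1.37 ± 0.112%. In replicate 4 the snRNA share was 1.05% (exact Clopper-Pearson 95% interval 1.04 to 1.05%), below 2.62% in replicate 1 (2.62 to 2.63%), 2.49% in replicate 2 (2.48 to 2.50%) and 2.82% in replicate 3 (2.81 to 2.83%). The expressed genes of these classes numbered 81 snRNA, 217 snoRNA and 516 lncRNA genes.

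**Figure D4:**
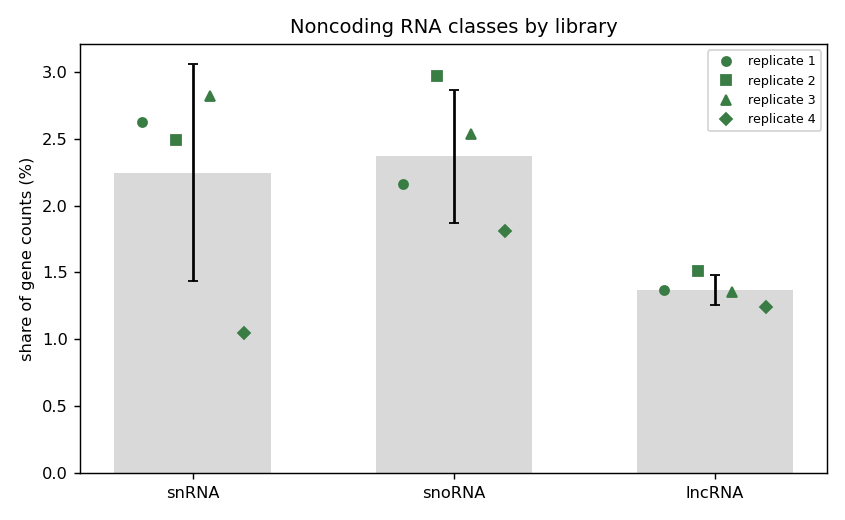
Share of gene counts in percent taken by snRNA, snoRNA and lncRNA genes; bars are means of 4 libraries, error bars the SD and symbols single libraries. The snRNA share of replicate 4 is 1.05%, and those of the other 3 libraries lie between 2.49 and 2.82%.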

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

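The tests of library totals, of snRNA gene number, of short RNA recovery, of histone genes and of the bx2 level were chosen after the results they concern had been seen; the test of fractional bx1 values was written down before its outcome was computed. Tests by thinning the libraries to equal depth, written down beforehand and run, are not used here because thinning leaves shares and ratios of abundant genes as they were.

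In each of 163 values given per library, the highest or lowest of the 4 libraries was compared with the other 3, and 12 values had a library set apart from the rest by more than Dixon's 95% critical ratio. Chance gives about 1 in 20 such values where they are independent and not picked for spread. Here list positions share genes with the named genes, and some named genes, LOC111590671 and LOC111591483 among them, were picked for high spread. The number flagged is thus no test against chance. In replicate 1 the photosynthesis list stood at 3.87 against 3.23 to 3.28 in the others and pep4 at 215 CPM against 135 to 146. As pep4 is the middle one of the 3 expressed members, both values report the same gene. In the same library sus1 stood at 1289 CPM against 755 to 785 and the RNA-dependent RNA polymerase gene rdr6 at 30.3 CPM against 18.9 to 19.3. In replicate 2 the chlorophyll-binding protein gene Cab-m7 stood at 5.13 CPM against 2.72 to 3.04. In replicate 3 the cyclin gene cyc3 stood at 24.3 CPM against 27.9 to 28.3. In replicate 4 the linker histone gene hon110 stood at 309 CPM against 218 to 226, the origin recognition gene orc4 at 29.8 CPM against 22.4 to 23.3, Bx7 at 923 CPM against 756 to 784 and cycD2 at 368 CPM against 429 to 437. The snRNA genes LOC111590671 and LOC111591483 stood in replicate 4 at 460 CPM against 1729 to 1831 and at 340 CPM against 1225 to 1266.

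The lower snRNA level of replicate 4 extended beyond these genes, since 73 of 81 expressed snRNA genes (90.1%, where chance gives 25% for independent genes) were lowest there. That argues against a few annotated genes setting the share. Where snRNA genes have near-identical copies, shared reads could make many of them move together, so a few kinds of snRNA are not excluded. The bootstrap over genes below has the same limit. Library depth as the whole cause was argued against as well: the total of replicate 4 (13621306 counts) lay between those of the other libraries, yet its share of 1.05% (exact 95% interval 1.04 to 1.05%) lay below their 2.49 to 2.82%, and replicate 3, with a total 1.41% higher, had a share of 2.82%. A loss of all short RNAs alike was tested with snoRNA genes, whose median log2 ratio of replicate 4 to the others was -0.16 against -1.11 for snRNA genes. The difference of 0.96 (95% bootstrap interval over genes 0.82 to 1.10) argues against equal loss as the whole cause, although 93 of 217 snoRNA genes were also lowest in replicate 4. A step of library preparation that acts on snRNA in particular may remain as an explanation; it was not tested, and with 1 group no biological explanation was tested.

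Replicates 1 and 2 differed in opposite directions in the glycolysis genes, a group chosen after the data had been seen, and the cytosolic ribosomal protein genes. As ratios to the median gene of each library, 9 of 10 expressed glycolysis genes were higher in replicate 1 (median log2 difference 0.31) and 35 of 37 ribosomal protein genes in replicate 2 (0.31); in CPM the numbers were 10 of 10 (0.40) and 29 of 37 (0.22). The list median of ribosomal proteins was highest in replicate 4, at log2 ratios of 4.23, 4.60, 4.29 and 4.70 in replicates 1 to 4, and glycolysis stood at 7.02, 6.74, 6.94 and 6.83. The gap between the list medians was thus 2.79, 2.14, 2.65 and 2.13. Fewer reads alone would leave ratios of abundant genes as they were. Whether the gap goes with the library total in another way stays open. Replicates 1 and 2 have the highest and lowest totals. Between replicates 3 and 4, whose totals differ by 1.41%, the gap differed by 0.52 (95% bootstrap interval over genes -0.09 to 0.65). It differed by 0.18 (-0.03 to 0.34) when each gene was compared with itself. Between replicates 1 and 2 these differences were 0.65 and 0.62. Unequal recovery of short transcripts could raise ribosomal protein genes, and histone genes, which are also short, had ratios to the median gene that were higher in replicate 2 by 0.32 (95% bootstrap interval over genes 0.06 to 0.42), in 9 of 11 cases; in CPM 7 of 11 were higher there (0.23). That interval includes values under 50% of the ribosomal protein difference, so this explanation stays open too, and with 1 group no biological explanation was tested.

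The benzoxazinoid gene bx1 had 1 count over 4 libraries, for which the upper 95% limit is 5.57 counts, while bx2, the lowest expressed member of the list, had 192. At the level of bx2 the depth would thus have sufficed to see bx1, which argues against depth as the cause. Reads of bx1 divided with or lost to a near-identical gene might also give a low count. bx1 had a fractional value in 0 of the 4 libraries, which decides nothing at 1 count, so this stays open without sequences, and no biological explanation was tested.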

How the results depend on the processing

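The restriction to genes with whole values and the detection by 1 count in transcription factor and other groups of the closing observations were chosen after the data had been seen; the other alternatives were planned. No paired analysis was possible because the labels give 1 group only. The planned comparison of length-corrected values with CPM was not run, since the reference gave no transcript lengths and CPM was used throughout. Of the results that answer a comparison, 305 values under an alternative kept their direction and side of the threshold, or for gene counts and untested values stayed near the main value. That leaves out the list pairs and the shares of the shortest lists, whose tests cannot pass 0.05; of the values for pairs 106 kept their direction and 2 did not. TMM scaling gave 5381 genes above and 5662 below, DESeq2 size factors 5383 and 5664, the DESeq2 Wald test 5320 and 5549, limma 5423 and 5914, a minimum of 1 CPM 5519 and 5931, whole-valued genes 4778 and 4994, and single left-out replicates 5202 to 5464 and 5439 to 5829. Without the 2-fold threshold the counts were 9312 and 9917. With every gene that had a count they were 8745 and 12774, because that setting adds low genes and lowers the median gene. The same setting moved the positions of cyclin D to 0.80, organelle ribosomal proteins to -2.27, root cap to 4.47, root hair to 3.02 and lignin and secondary wall to -4.70 (now past the threshold), ended the calls of nutrient and water uptake (0.37) and hypoxia and heat response (0.39), and reversed the Casparian strip (0.16), photosynthesis (-5.06), DNA replication minus photosynthesis (8.07) and photosynthesis minus seed storage (-0.88). With 1 count as detection, the shares expressed were 100% for DNA replication, mitosis, and DNA methylation and small RNA (none now past the threshold), 47.1% for root patterning, 96.9% for cytokinin and 94.6% for hypoxia and heat response (now past it), and 77.27% for lignin and 85.1% for uptake (reversed, against 77.26% of all protein-coding genes); the larger share of all genes follows from the setting. Among the groups added later it ended the results for MYB (75%) and MADS genes (58.6%) and reversed homeobox (85.0%), TIFY and ZIM (90.5%) and secondary wall cellulose synthase genes (100%), none of which had passed. Hypoxia and heat response also lost its call with a minimum of 1 CPM (0.90), with whole-valued genes (0.77) and without any 1 of the 4 replicates (0.95 to 1.01). The list mean ended the calls of uptake (0.68), photosynthesis (2.22) and seed storage (-1.66), and whole-valued genes those of uptake (0.83) and seed storage (-2.31). Seed storage also lost its call without replicate 3, in a range of -2.90 to -2.46 over left-out replicates. For these changes of call the cause was not tested. The common BCV was 0.118 to 0.145 over left-out replicates. Of the named genes none reversed where either value had a call. A change of sign between values without a call was counted as no change. Of the values for named genes 53 gained a call, 25 of them without the 2-fold threshold and 18 without the expression filter. A call was lost by 23, 10 of them without the expression filter. A minimum of 1 CPM added the calls of orc1, SLD5 and rmr7, and whole values those of SLD5 and rmr7. The DESeq2 Wald test ended 2 calls, wox13A and GLB1, and limma added 1, orc1 (adjusted p = 0.0388). Depth limits statements on absence to 0.0584 CPM over the 4 libraries.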

Other observations

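The 15 gene groups and their tests in this part were all chosen after the data had been seen, and members were taken by gene symbol.

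Cellulose synthase genes of growing walls were high in the root tip. All 9 genes CesA-1 to CesA-9, whose products build the primary wall, were expressed, and 8 lay above the median gene by the edgeR test against a 2-fold difference, with a median log2 ratio of 2.90 ± 0.12 (SD, n = 4). CesA-2 stood at 261 ± 55.4 CPM, CesA-9 at 250 ± 34.1 CPM and CesA-8 at 214 ± 27.3 CPM, while CesA-3 at 21.1 ± 3.38 CPM did not pass. None of the 3 genes of the secondary wall was expressed, with 1 count for cesa10, 24 for cesa11 and 14 for CesA12 over 4 libraries. These genes are also on the lignin and secondary wall list, so they add no separate evidence to it. Glycolysis genes were among the most abundant, with 10 of 11 expressed, 9 above and a median log2 ratio of 6.88 ± 0.12. The aldolase gene ald1 stood at 1968 ± 346 CPM, the enolase gene eno1 at 1783 ± 323 CPM and the phosphoglycerate kinase gene Pgk-2 at 1818 ± 150 CPM, while Pgk-1 had 15 counts and pfk1, a phosphofructokinase gene, stood at 9.20 ± 1.72 CPM. The shares expressed did not pass over 15 groups for either wall group or for glycolysis (Fisher's exact test, adjusted p = 0.0641, 0.190 and 0.0913).

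Genes of the MYB and MADS families passed the expression filter less often than protein-coding genes as a whole. Of 40 MYB genes 10 were expressed and of 29 MADS genes 6, both under the share of all protein-coding genes (Fisher's exact test, adjusted p = 0.00055 and 0.000622). The difference depended on the expression filter: where 1 count sufficed, 30 of 40 MYB genes (75%) and 17 of 29 MADS genes (58.6%) were detected, against 77.3% of all protein-coding genes, and neither passed (adjusted p = 0.758 and 0.185). MYB112 stood out within its family at 132 ± 12.9 CPM, where the next, myb31, stood at 11.2 ± 0.683 CPM, and the highest MADS gene, MADS62, stood at 9.07 ± 0.648 CPM. The other families did not pass over 15 groups, with 28 of 46 bHLH, 22 of 30 bZIP, 14 of 22 WRKY, 17 of 26 NAC, 24 of 35 ethylene response factor, 10 of 20 homeobox, 3 of 4 GRAS, 4 of 7 TCP and 12 of 21 TIFY and ZIM genes expressed. The adjusted p of these ran from 0.207 to 1 by Fisher's exact test. Methyl-CpG-binding protein genes were expressed in 10 of 11 cases (adjusted p = 0.0913, Fisher's exact test). Only genes with a family symbol were counted, so these shares do not describe whole families.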
